A study of Mus musculus with 9 samples.

How the data were processed

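Gene expression was measured by stranded mRNA sequencing (TruSeq) in 9 libraries of sorted mouse cells, 5 of the group labelled Lef1KI and 4 of the group labelled WT. Per the labels' protocols, primary tracheal gland cells were pooled from 3 to 5 mice that carried a tamoxifen-inducible Cre driven by Acta2, a smooth muscle actin gene that myoepithelial cells express, together with either a Lef-1 knock-in allele (Lef1KI) or the ROSA-TG allele (WT). The mice received tamoxifen on each of 5 days before harvest. Cells were grown to passage 1 on plastic coated with laminin-rich conditioned medium, in airway medium with the inhibitors DMH-1 (of BMP receptors) and A83-01 (of TGF-beta receptors) and a GSK3 inhibitor that activates Wnt/beta-catenin signalling, each at 1 µM, and with Y-27632 at 10 µM. The labels call the sorted cells lineage-tagged myoepithelial cells, taken as GFP-positive from WT cultures and as GFP-negative from Lef1KI cultures, so the gate and the genotype change together in every library. The labels state RNA integrity numbers above 10, although that scale ends at 10. The genetic background of either line is not given in the sources used here.

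The deposited table holds log2(TPM + 1) values, where TPM is a gene's share of all transcripts, scaled to a fixed total. Per the submitters' processing notes the authors used RSEM and the mm10 build; the RSEM version, the aligner and the annotation release are not given in the sources used here. The unit was checked on the values. Here 2 raised to a deposited log2 value, less the pseudocount of 1, came out in whole hundredths of a TPM for 100.0% of values under 50 TPM (tolerance 0.01 of a hundredth), and each library summed to between 99.6% and 99.84% of the total that the TPM of all transcripts reach. The table holds 13336 genes. From the values, the authors had kept genes whose mean was at least 3 SD in at least 1 of the groups (lowest 3.002), which favours genes with little spread; 1683 of the genes lay below 3 SD in 1 group. Depth cannot be recovered, because TPM keeps no read counts, so no counting error is given and the spread between libraries is the error used throughout. The authors' own columns of group mean and SD, in log2 units, equal the values recomputed here up to rounding. Deposited columns carry letters (Lef1KI A to E; WT A, B, E and D) and the labels carry replicate numbers, and nothing ties a letter to a number: columns were assigned to groups by name, and libraries are called by letter. Symbols, positions and gene types come from GENCODE M21 on mm10, in which 13280 gene IDs (99.58%) were found.

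Each library is 1 pool of mice by the labels, so the p-values measure the spread between pools. No sequencing date or batch is given in the sources used here. Library pairs were compared for duplicates, and none held the same values: exactly equal values were found for at most 92 of the 13336 genes in any pair.

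Groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior (limma-trend), on the deposited log2 values of all 9 libraries, without a further filter and with group as the only term. P-values are two-sided with Benjamini-Hochberg adjustment over the 13336 genes, and a gene is said to have changed, risen or fallen at an adjusted p under 0.05. Differences are Lef1KI minus WT on the log2(TPM + 1) scale, which understates the change of genes near 0 TPM. Lef1 was also tested by an exact two-sided permutation test over all splits of the libraries into 5 and 4. The count models planned in case the table held counts could not be applied to TPM.

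Before the data were examined, 42 gene lists (cell types, pathways, stress and RNA quality), the tests, the rule for named genes and most of the alternatives were fixed. Lists with at least 5 measured members (41 of them) were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists by Benjamini-Hochberg; camera compares a list with all other genes, whose median difference was 0.14 rather than 0. Camera with an estimated correlation and fry, which asks whether a list's own genes move on balance in 1 direction without comparing them with other genes, were alternatives. For each list the count of members past the all-genes threshold is given beside the count adjusted over the list alone. The rule names Lef1, Acta2, Krt5, Krt14, Trp63 and Axin2. It then names the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, an absolute log2 difference of at least 1, no overlap between groups and a mean in the higher group above the median of all genes (3.80). From each list it adds up to 2 members per direction with the smallest adjusted p. Gene models without a descriptive symbol are counted, not named; other genes were chosen after their values were seen, as stated beside them. The value of 1 gene of the club and secretory list is not reported here.

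The alternatives fixed then were median centring, a trimmed-mean scaling of the linear values, TPM filters of 1 and of 10 in at least 4 libraries, pseudocounts of 0.1 and 5, limma without the trend, robust limma, sample quality weights, a test against a log2 fold change of 1, adjusted p thresholds of 0.01 and 0.1, and leaving out each library in turn. A block on replicate number was also named then and was not run, because nothing ties a column letter to a number. Added after the data were seen were protein-coding genes alone, the mean of the fibroblast list as a covariate, and an exact permutation test of each list's mean against that of all genes. Gene copies were matched to protein-coding genes with blastn 2.17.0 (at least 90% identity over at least 50% of the copy), and a family was tested when its changed copies moved by at least 10% of the level of the related gene.

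The model was tested on simulated tables of 13336 genes for Lef1KI against WT. Of 50 genes changed at each size it recovered 12% at a true log2 difference of 0.5, 76% at 1, 92% at 2 and 100% at 4, and it called 7 unchanged genes beside them. The changed genes were drawn from those with a mean log2(TPM + 1) above 2, so recovery at lower levels is not shown. In a table with no change the model called 0 of 12619 genes, with 5.18% of genes at an unadjusted p under 0.05, and 0 lists. Genes were drawn independently there, so the 0 lists show nothing about lists whose members vary together, as the fibroblast genes did within groups. For the same reason the 0 of 12619 genes does not cover genes that vary together.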

Results

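The series asks what forced expression of the transcription factor Lef1, an effector of Wnt signalling, does to myoepithelial cells of the mouse trachea that have been expanded in culture. Myoepithelial cells are contractile basal-type cells that wrap the glands of the airway. RNA of 5 Lef1KI and 4 WT libraries was compared as TPM on a log2 scale. Median log2(TPM + 1) per library lay between 3.58 and 3.97, and between 11465 and 12135 genes reached 1 TPM. The first principal component carried 48.2% of the variance and separated the groups, with all 5 Lef1KI libraries at negative scores and all 4 WT libraries at positive scores.

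Lef1 itself was on in every Lef1KI library and nearly absent from every WT library. The gene (ENSMUSG00000027985, chromosome 3 from 131110471 to 131224356 on the plus strand, mm10) had 227 ± 79.8 TPM in Lef1KI (SD, n = 5) and 0.448 ± 0.0763 TPM in WT (SD, n = 4). Libraries Lef1KI A to E had 210.1, 311.5, 308.8, 139.3 and 166.2 TPM, and WT A, B, E and D had 0.55, 0.46, 0.40 and 0.38 TPM. The difference was 7.23 on the log2 scale (SE 0.236, limma adjusted p 5.2e-08, exact permutation p 0.0159, the smallest the design allows). The values do not separate transcripts of the knock-in allele from those of the endogenous gene. Among the genes fixed for naming, basal cell genes were high in both groups. Krt5 and Krt14, the keratins of basal and myoepithelial cells, had 8586 ± 829 and 7217 ± 457 TPM in Lef1KI against 7008 ± 2442 and 6258 ± 362 TPM in WT, and Trp63, the basal cell transcription factor, had 108 ± 14.9 against 117 ± 7.51 TPM (limma adjusted p 0.325, 0.31 and 0.53). Acta2, the smooth muscle actin whose promoter drives the Cre, had 62.3 ± 31.2 TPM in Lef1KI and 129 ± 41.0 TPM in WT, a difference of −1.13 that did not pass the threshold (limma adjusted p 0.0834) although it did without Lef1KI C, where the difference was −1.36. Axin2, a feedback target of Wnt/beta-catenin signalling, had 8.52 ± 2.46 against 12.2 ± 2.28 TPM (log2 difference −0.49, limma adjusted p 0.177).

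**Figure D1:**
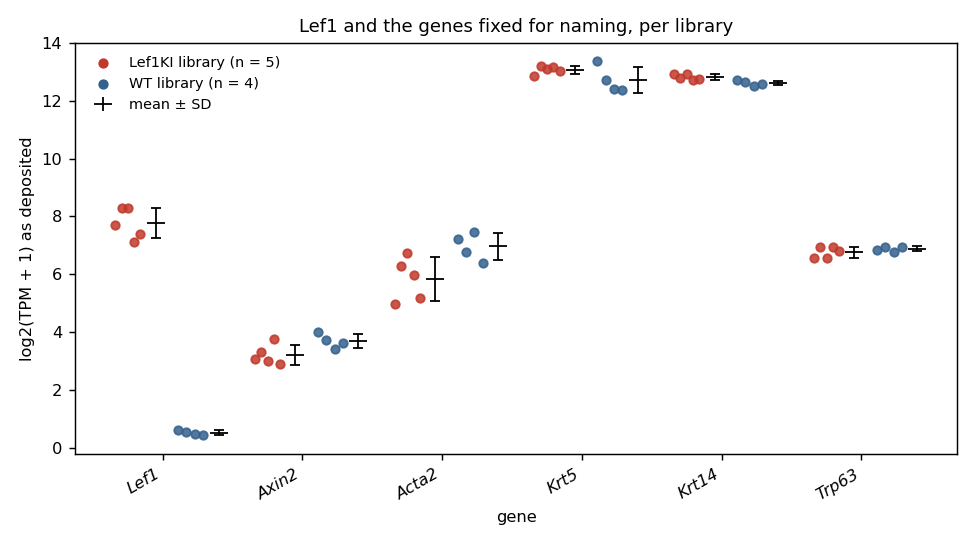
Deposited log2(TPM + 1) of Lef1 and of 5 genes fixed for naming, per library, with group means ± SD beside the points (red for the 5 Lef1KI libraries and blue for the 4 WT libraries). Lef1 separates the groups by 7.23, while Krt5, Krt14, Trp63, Acta2 and Axin2 did not pass the threshold.

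Of 13336 genes, 1063 changed, 898 higher and 165 lower in Lef1KI (84.5% higher). Among the genes the naming rule takes, the lipocalin gene Apod had the largest rise after Lef1, from 17.1 ± 7.64 to 394 ± 207 TPM (log2 difference 4.33 ± 0.45 SE, limma adjusted p 0.000522, chromosome 16 from 31296192 to 31314808). Gene models without a descriptive symbol, 12 higher and 12 lower among those that met the rule's other conditions, are left out of this ranking. Some gene models rose more, by up to 9.96 on the log2 scale. The lymphoid chemokine gene Cxcl13 rose from 7.27 ± 7.45 to 145 ± 101 TPM (log2 difference 4.15, limma adjusted p 0.00272). The guanylate-binding protein gene Gbp2b (log2 difference 3.93), the monocyte chemokine Ccl8 (3.09), the membrane protein gene Ms4a4d (2.95), the serpin Serpina3g (2.94), the collagen VI chain Col6a3 (2.88) and the matrix protein gene Sparcl1 (2.81) followed. Arg1, which encodes the arginine-degrading enzyme arginase, fell by 2.50 on the log2 scale, and so did the stratum corneum protease gene Klk7 (−2.46), the beta-defensin gene Defb14 (−2.32), Lypd5 (−2.29), the dual oxidase maturation factor gene Duoxa1 (−2.22, 19.1 ± 4.0 against 95.3 ± 28.9 TPM) and Hddc3 (−2.06). For each of these genes every Lef1KI library lay on the same side of every WT library, which the naming rule requires. The cytokine gene Tslp (log2 difference 3.64) and the lectin receptor gene Klra4 (2.94) were also among the 10 largest rises. Tslp passed in only 1 of the 9 fits that left out a library, the one without Lef1KI A (differences between 3.06 and 4.52), and Klra4 missed the threshold without WT B (2.74) or WT E (2.75). Arg1 missed it without Lef1KI C (−2.30) or WT E (−2.22), and Lypd5 in 6 of the 9 fits (differences between −2.70 and −1.89). The largest falls also included 4 gene copies (Eno1b, Vcp-rs, Rbpsuh-rs3 and Rpl3-ps1) that are described last. At an absolute log2 difference of at least 1 there were 463 rises and 79 falls, and 966 of the changed genes had groups that did not overlap. Over all genes 11.92% did not overlap, where chance gives 1.59% for genes not selected on the groups. The authors' filter used the real groups, so the share that chance gives in this table is unknown. The balance of rises and falls depended on scaling: with each library centred on its median, 937 genes changed, 605 higher and 332 lower (64.6% higher, 769 shared with the values as deposited). With trimmed-mean scaling it was 712 higher and 265 lower (72.9%, 875 shared). The median log2 difference of all genes was 0.141 as deposited, −0.018 with median centring and 0.02 with trimmed-mean scaling. The count was 628 without WT E, 643 without WT B and 1686 without Lef1KI A.

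Genes of fibroblasts and other stromal cells were higher in Lef1KI as a group. Of 16 measured members, 15 rose and 16 did so adjusted over the list alone, with a median log2 difference of 1.96. They included structural collagens and matrix proteins: Col6a3 rose from 8.71 ± 2.64 to 73.1 ± 29.3 TPM, Col1a1 from 4.97 ± 1.22 to 40.4 ± 17.6 TPM, and, chosen after their values were seen, Dcn from 44.0 ± 14.9 to 305 ± 133 TPM and Mgp from 583 ± 261 to 2263 ± 911 TPM. The receptor genes Pdgfra and Pdgfrb, also chosen afterwards, rose by log2 1.81 and 1.97. WT cells were not devoid of these transcripts, since 15 of the 16 had a WT mean of at least 1 TPM. Endothelial genes moved the same way at lower levels: 9 of 13 rose (11 adjusted over the list alone, median log2 difference 1.79), among them Ramp2, from 1.35 ± 0.593 to 9.08 ± 2.59 TPM, and Plvap, from 0.388 ± 0.223 to 2.53 ± 0.818 TPM. Of the list, 4 of the 13 had a WT mean of at least 1 TPM. Of 6 leukocyte genes, 2 rose, Lyz2 (log2 difference 1.95) and Coro1a (0.45, with calls lost under median centring and without WT B or WT E, at differences of 0.45 and 0.39). The leukocyte list, with 3 of its 6 genes at a mean of 1 TPM or more in each group, had a median of 0.075, which became −0.085 under median centring, and 3 of its genes were higher and 1 lower adjusted over the list alone. Camera called the fibroblast and endothelial lists (adjusted p 1.28e-15 and 1.99e-06) and not the leukocyte list (0.776). With an estimated correlation neither call held (camera adjusted p = 0.522 with an estimated correlation for both, over all alternatives 1.03e-20 to 0.951 and 1.78e-08 to 0.522). Lef1KI libraries were sorted as GFP-negative and WT libraries as GFP-positive, so these differences belong to the gate and the genotype together.

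**Figure D2:**
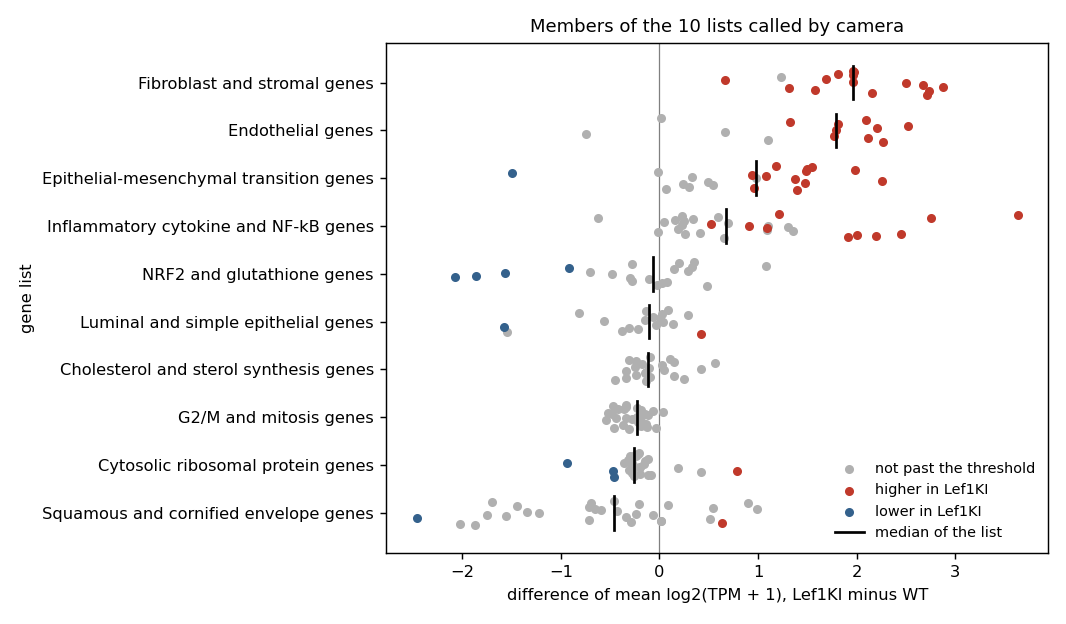
Difference in mean log2(TPM + 1), Lef1KI minus WT, of every measured member of the 10 lists that camera called (points, red where higher, blue where lower and grey where not past the limma threshold, with black bars at list medians). The fibroblast list has its median at 1.96 and the endothelial list at 1.79, while the medians of the 6 lists below lie between −0.46 and −0.06, and 3 of these (luminal, sterol and NRF2) turn positive when 1 library is left out.

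Of 21 measured genes of epithelial-mesenchymal transition 12 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 difference of 0.98. The transcription factor gene Twist2 rose from 0.848 ± 0.455 to 6.43 ± 2.37 TPM and the matrix gene Sparc from 187 ± 31.2 to 357 ± 35.9 TPM. Twist1, Zeb1, Vim and Mmp2, chosen after their values were seen, rose by log2 1.49, 1.55, 1.5 and 2.25. Tgfbi, a matrix protein gene induced by TGF-beta, fell by 1.49, a call that held in 4 of the 9 fits that left out a library. Cdh1, the epithelial cadherin gene at the other end of this transition, was higher in Lef1KI (363 ± 20.02 against 270.2 ± 12.5 TPM, log2 difference 0.43), a call that ended under both scalings and without WT B, where the difference was 0.39. Camera called the transition list (adjusted p 1.11e-06), and the call was lost with an estimated correlation (camera adjusted p = 0.522 with an estimated correlation, 1.08e-08 to 0.731 over all alternatives). Among 23 basement membrane and matrix genes 8 rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p 0.2): Col4a1 and Col4a2, the chains of the collagen IV network, rose by log2 2.22 and 2.20 to 205 ± 47.1 and 144 ± 36.4 TPM, and Fbln1 fell by 0.54 in a call that held in 2 of the 9 fits. Integrin genes showed 5 rises and 1 fall in 23 (6 and 1 adjusted over the list alone, camera adjusted p 0.257), led by Itga8 (log2 difference 1.56) and Itga9 (1.03), with Tns4 lower (−1.11, held in 2 of the 9 fits). In the TGF-beta and BMP list 5 of 27 rose (7 higher and 2 lower adjusted over the list alone, camera adjusted p 0.776), among them the activin gene Inhba (log2 difference 1.96) and the receptor gene Tgfbr2 (0.98). The fibroblast list was higher in these same 5 libraries, by the median of 1.96 given above.

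**Figure D3:**
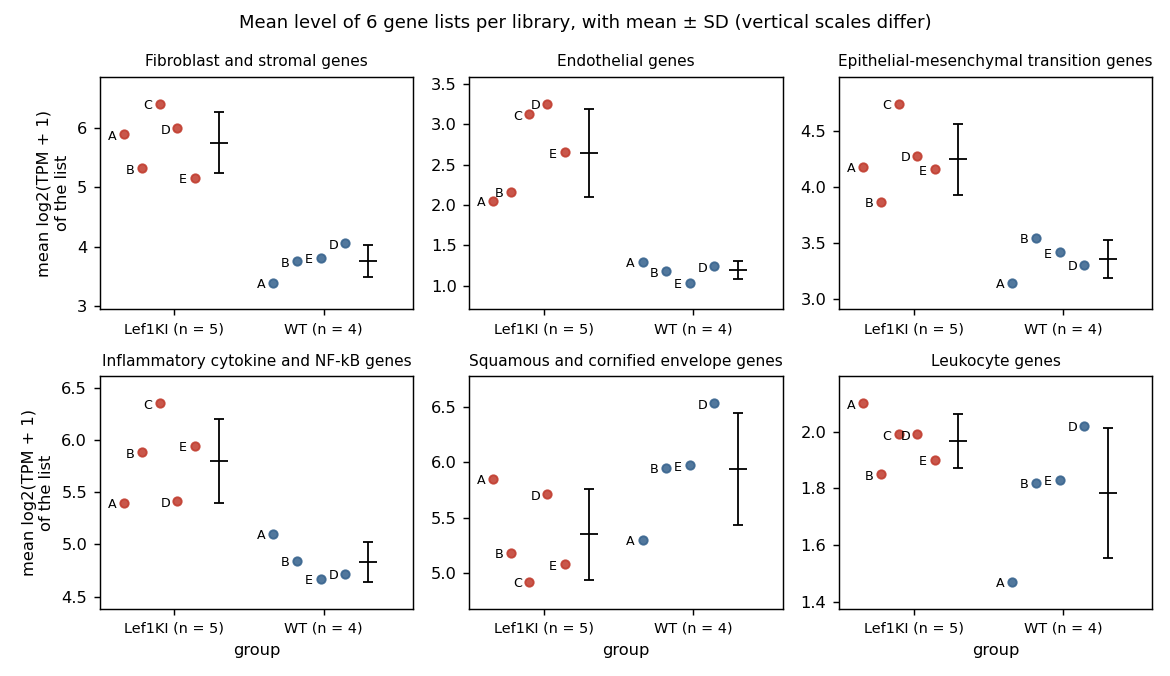
Mean log2(TPM + 1) of 6 gene lists in each library, with library letters, group means and SD (red for the 5 Lef1KI libraries and blue for the 4 WT libraries, on vertical scales that differ). The fibroblast, endothelial, transition and inflammatory means do not overlap between groups, whereas the squamous and leukocyte means do.

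Some inflammatory genes also rose. Of 28 measured cytokine and NF-kB genes, 10 rose (15 adjusted over the list alone), with a median log2 difference of 0.68. The acute phase gene Saa3 rose from 324 ± 143 to 2310 ± 1100 TPM and the chemokine gene Ccl7 from 8.39 ± 2.71 to 39.0 ± 22.1 TPM. Ccl2, Ccl20 and Csf3, chosen after their values were seen, rose by log2 1.91, 2.20 and 2.45. With median centring and with trimmed-mean scaling, 5 and 6 of the list's genes rose. Camera called the list (adjusted p 0.000304), and the call was lost with an estimated correlation (camera adjusted p = 0.522 with an estimated correlation, 6.18e-06 to 0.522 over all alternatives). Interferon genes were not called as a list: 0 of 28 passed limma's threshold, 1 had an unadjusted p under 0.05, and neither camera (adjusted p 0.939) nor fry (0.683) called it. Antigen presentation genes gave 0 of 15 with 3 at an unadjusted p under 0.05 (camera adjusted p 0.681, fry 0.683). The fibroblast list was higher in the same 5 libraries (median log2 difference 1.96).

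A minority of Wnt pathway genes rose, among them feedback inhibitors, secreted inhibitors, receptors and R-spondins. Of 14 measured target and feedback genes, 3 rose, all of them inhibitors of the pathway (3 adjusted over the list alone): Apcdd1, from 3.72 ± 0.824 to 9.46 ± 2.78 TPM (limma adjusted p 0.00826), Nkd2, from 1.82 ± 0.331 to 4.94 ± 1.48 TPM (0.00731), and, chosen after its value was seen, Notum (log2 difference 0.47). The list as a whole had a median log2 difference of 0.09 and was not called by camera (adjusted p 0.938), though fry, which does not compare it with other genes, called it higher (0.0404). Of 31 ligands, receptors and secreted inhibitors, 7 rose (12 higher and 1 lower adjusted over the list alone, camera adjusted p 0.0977, fry 0.00386). The inhibitor gene Sfrp2 rose from 1.49 ± 0.274 to 6.26 ± 1.83 TPM and the receptor gene Ror1 from 2.94 ± 0.562 to 7.97 ± 1.35 TPM. Rspo1 and Rspo3, secreted proteins that potentiate Wnt signalling, rose by log2 1.17 and 1.11 and were chosen after their values were seen. Of 16 TCF/LEF partners and co-repressors, Tle4, a Groucho co-repressor gene, rose by log2 0.93 (2 adjusted over the list alone, camera adjusted p 0.186, fry 0.0328), a call that was lost without WT E (log2 difference 0.86). Median centring turned the median of the target list to −0.07 and left 2 of its 3 calls. Both groups were cultured with a GSK3 inhibitor, and the fibroblast list was higher in the same 5 Lef1KI libraries (median log2 difference 1.96).

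Few epithelial identity genes passed the threshold, while most genes of squamous differentiation had lower values in Lef1KI. Of 22 airway basal cell genes, 2 rose and 1 fell (the same adjusted over the list alone, camera adjusted p 0.102): Sfn (log2 difference 0.73), Cdh3 (0.48) and the nerve growth factor receptor gene Ngfr (−1.07), which kept their calls in 6, 3 and 5 of the 9 fits that left out a library. Both scalings ended the call of Cdh3. Of 20 contractile genes of myoepithelial and smooth muscle cells, Synm, an intermediate filament gene, fell from 4.02 ± 1.16 to 1.23 ± 0.423 TPM, and Mylk rose (log2 difference 0.71) in a call that held in 2 of the 9 fits and under neither scaling. Adjusted over the list alone 2 contractile genes were higher and 4 lower, and the list was not called (camera adjusted p 0.654, median log2 difference 0.24, although camera placed it below other genes). In the squamous and cornified envelope list, 21 of 29 members had negative differences, with a median of −0.46 (−0.30 without WT B). Klk7 fell and Dsc1, a desmosomal cadherin gene, rose (1 and 1 adjusted over the list alone). Dsc1 had a mean under 1 TPM in each group, and its call held in 2 of the 9 fits and under neither scaling. Cnfn and Krt13, chosen after their values were seen, had 109 ± 108 and 343 ± 169 TPM in Lef1KI against 374 ± 204 and 1301 ± 1048 TPM in WT, differences that did not pass. Camera called this list lower (adjusted p 5.79e-06), a call lost with an estimated correlation (camera adjusted p = 0.522 with an estimated correlation, 4.22e-07 to 0.522 over all alternatives).

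Luminal epithelial genes were called lower by camera (adjusted p 0.0176, camera adjusted p = 0.549 with an estimated correlation, 0.00266 to 0.683 over all alternatives), but the call was lost without Lef1KI A (camera adjusted p 0.0522) or WT D (0.0743) and under median centring (0.059). The 18 members held 1 fall, the transcription factor gene Elf3 (log2 difference −1.58, called in 4 of the 9 fits), and 1 rise, Cdh1 (2 lower and 1 higher adjusted over the list alone). The median log2 difference of −0.10 was 0.022, −0.031 and −0.19 without Lef1KI A, B or E, and −0.26 and −0.017 without WT A or D. Genes of glutathione metabolism and the NRF2 response were also called lower (camera adjusted p 0.00846, camera adjusted p = 0.522 with an estimated correlation, 0.000724 to 0.931 over all alternatives), a call lost without Lef1KI D (camera adjusted p 0.0685). Their median of −0.064 was −0.038, 0.009 and −0.17 without Lef1KI A, D or E, and −0.13 and −0.11 without WT E or D. Of 20 members 4 fell (5 lower and 1 higher adjusted over the list alone): the quinone reductase gene Nqo1 (−0.91), Gsta2 (−1.86) and, chosen after their values were seen, Gsta1 (−2.07) and Gsta4 (−1.57), the last 3 being glutathione transferase genes among which reads could be split. Nqo1 and Gsta2 kept their calls in 4 and 6 of the 9 fits. Other lists of gland and airway cells were not called by camera. Of 11 club and secretory genes 3 rose, among them Hp and Fmo2 (log2 differences 2.55 and 2.54), and Gsto1 fell (−0.77, held in 4 of the 9 fits), with a median of −0.38 and a mean of 0.24 (3 higher and 4 lower adjusted over the list alone, camera adjusted p 0.435). Of 7 mucous and serous genes Lpo rose (0.69, held in 4 of the 9 fits and lost under median centring) and Pigr fell (−0.64), 1 and 1 also adjusted over the list alone (camera adjusted p 0.245). Of 6 ciliated cell genes Cfap126 fell (−0.75, held in 4 of the 9 fits, 1 adjusted over the list alone, camera adjusted p 0.654). Of 21 gland bud genes Bmp4 rose (0.96) and Pitx1 and Barx2 fell (−0.68 and −0.88), in calls that held in 3, 5 and 3 of the 9 fits (2 and 2 adjusted over the list alone, camera adjusted p 0.157). In the stem and progenitor list, 19 measured, Thy1 (log2 difference 2.28) and Nrp1 (0.82, held in 3 of the 9 fits and under neither scaling) rose and Aldh1a3 fell (−1.91, held in 5), against 3 and 3 adjusted over the list alone (camera adjusted p 0.12).

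G2/M, ribosomal and sterol genes had small differences that camera called as lists. Of 30 G2/M genes 29 were lower in Lef1KI, with a median log2 difference of −0.23. The median was −0.051 without WT A (camera adjusted p 0.00387) and −0.36 without Lef1KI E. The list mean was 5.59 in WT A against 4.91 to 5.08 in the other WT libraries, and the groups overlapped, with 5.04 in Lef1KI B and 5.35 in Lef1KI E. Of all 30 genes 0 passed limma's threshold, over all genes or adjusted over the list alone, and 6 had an unadjusted p under 0.05 (camera adjusted p 3.09e-08, camera adjusted p = 0.534 with an estimated correlation, 4.4e-12 to 0.534 over all alternatives, fry 0.432). With the fibroblast list mean as a covariate, chosen after the data were seen, camera called the G2/M list higher instead (adjusted p 7.17e-12). That mean had a correlation of 0.935 with the group, so this fit cannot separate the covariate from the group difference. Of 30 G1/S genes 0 passed and 1 had an unadjusted p under 0.05 (camera adjusted p 0.938, fry 0.653). Of 31 cytosolic ribosomal protein genes 28 were lower, with a median of −0.26 (camera adjusted p 1.42e-11, camera adjusted p = 0.522 with an estimated correlation, 1.66e-14 to 0.894 over all alternatives). Among them 3 fell (Rps18, Rpl30 and, chosen after its value was seen, Rpl10a) and Rpl3 rose, with the same counts adjusted over the list alone. Both scalings ended the call of Rpl3, and the calls of Rps18 and Rpl30 held in 6 and 7 of the 9 fits that left out a library. Of 22 sterol synthesis genes 0 passed, 1 had an unadjusted p under 0.05 and the median was −0.12 (camera adjusted p 0.0089, camera adjusted p = 0.676 with an estimated correlation, 1.55e-05 to 0.738 over all alternatives, fry 0.738), and the call was lost without Lef1KI D (camera adjusted p 0.27, median 0.013), while the median was −0.28 without Lef1KI E.

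The remaining lists were not called by camera. In the p53 and arrest list (24 genes, adjusted p 0.654) the cell cycle inhibitor gene Cdkn2a rose from 8.09 ± 2.02 to 16.3 ± 2.56 TPM. In the FGF and EGF list (21 genes, 0.881) the growth factor genes Fgf7 and Fgf10 rose by log2 1.22 and 1.16, as did Spry4 (0.86, chosen after its value was seen), and the phosphatase gene Dusp4 fell by 1.27 in a call that held in 3 of the 9 fits. In the YAP/TAZ list (19, camera 0.18, fry 0.0404) Foxf2 rose (0.83) and Nuak2 fell (−0.56, held in 3 of the 9 fits). Klf2 (1.48) and Nr4a1 (0.90, held in 4 of the 9 fits) rose in the immediate early and heat shock list (22, 0.408), and Atf3 (0.72) in the unfolded protein list (20, 0.681). Aqp1, a water channel gene, rose from 19.4 ± 9.25 to 88.2 ± 18.3 TPM in the ion and water transport list (11, 0.0616), with Best1 higher (0.75) and Car2 lower (−1.10). Adjusted over the list alone these lists had 1, 6, 2, 2, 1 and 2 genes higher and 0, 2, 1, 0, 0 and 3 lower, in the order given. In 8 lists limma called 0 genes over all genes tested. Notch pathway genes (14 measured) held 4 at an unadjusted p under 0.05, with a camera adjusted p of 0.368 and a fry adjusted p of 0.683. Hedgehog genes (12) held 4 (camera adjusted p 0.368, fry 0.111), and hair keratin genes (5) held 2 (camera adjusted p 0.601, fry 0.111). Glycolysis and hypoxia genes (23) held 2 (camera adjusted p 0.654, fry 0.653), oxidative phosphorylation genes (26) held 2 (camera adjusted p 0.637, fry 0.666) and mitochondrial genome genes (13) held 0 (camera adjusted p 0.493, fry 0.897). Schwann and neural genes (8) held 2 (camera adjusted p 0.0616, fry 0.146), and cartilage and muscle genes (8) held 2 (camera adjusted p 0.2, fry 0.774). The median and the mean of the mitochondrial genome list differed in sign (0.07 and −0.16), as did those of the immediate early list (−0.03 and 0.17) and of the stem and progenitor list (−0.14 and 0.05). Camera placed the ciliated, gland bud, p53, FGF and EGF, antigen presentation, glycolysis and oxidative phosphorylation lists below other genes although their medians and means were above 0. Adjusted over the list alone, 1 hair keratin gene was higher, 1 cartilage and muscle gene was higher and 1 was lower, and 0 passed in the others. Of the neuroendocrine and tuft cell list only 2 genes were measured, too few for a test. Dclk1 rose from 1.66 ± 0.323 to 5.80 ± 1.89 TPM (1 adjusted over the list alone).

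Near-identical copies of other genes made up many of the largest differences. Of 30 genes that changed by at least 3 on the log2 scale, 14 were annotated pseudogenes, against 324 pseudogenes among all 13336 genes (Fisher's exact p 1.93e-15). Several were present in 1 group and nearly absent from the other. Eno1b (chromosome 18 from 48045335 to 48048412), a copy of the enolase gene Eno1, had 0.148 ± 0.0626 TPM in Lef1KI and 47.3 ± 29.1 TPM in WT, and Vcp-rs (chromosome X from 104345829 to 104348234), a copy of Vcp, 0.118 ± 0.125 and 41.9 ± 26.5 TPM. Rbpsuh-rs3, a copy of Rbpj, fell by 3.46, and Rpl3-ps1 by 3.26 in a call that held in 2 of the 9 fits. Changes of the related genes are uncertain where reads could be divided between them and their copies. Rps18 had 3053 ± 780 TPM in Lef1KI against 5674 ± 544 TPM in WT, while its 4 changed copies together had 2281 against 4.91 TPM, and the totals were 5334 ± 585 and 5679 ± 545 TPM. For Csnk2a1, a casein kinase gene chosen after its value was seen, the gene had 80.6 ± 8.73 against 37.1 ± 11.6 TPM and the total with its copy was 84.6 ± 6.78 against 83.0 ± 6.50 TPM. The same uncertainty holds for Rpl3, Rpl30, Vcp, Ahcy and Cdh11, whose copies moved the other way, and for Klra4, Serpina3g and Gbp2b, which belong to families of close paralogs.

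**Figure D4:**
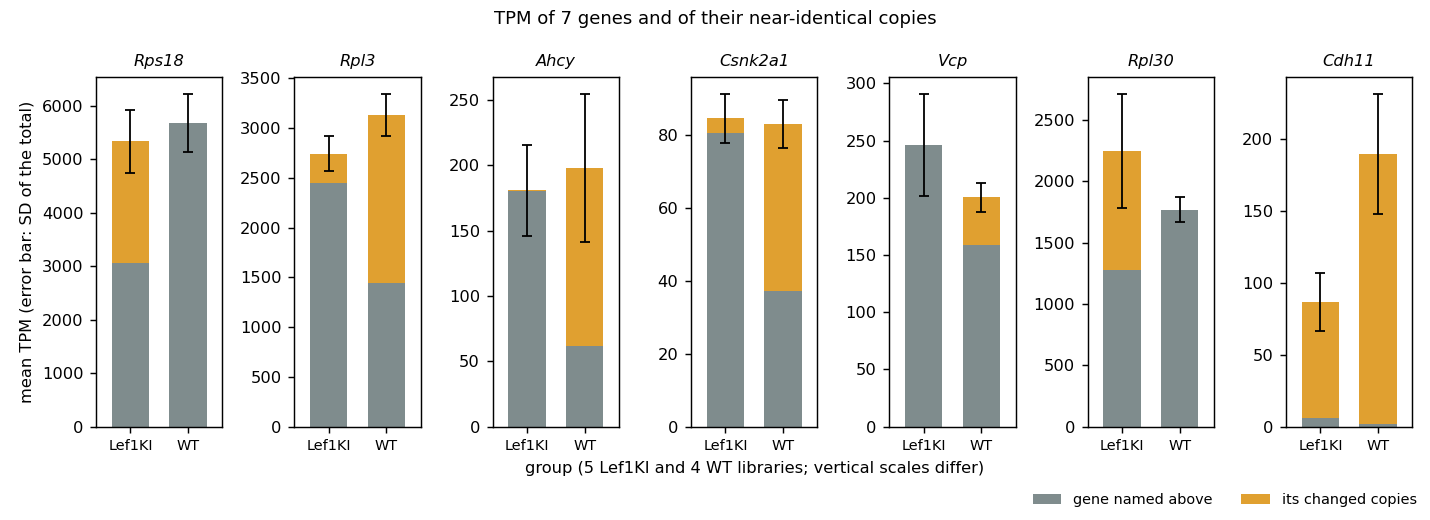
Mean TPM of 7 changed genes (grey) and of their changed near-identical copies (orange) in 5 Lef1KI and 4 WT libraries, stacked from 0, with error bars for the SD of the total (vertical scales differ). The totals of Rps18, Rpl3, Ahcy, Csnk2a1 and Vcp differ by less than 0.5 of the named gene's own log2 difference. Those of Rpl30 and Cdh11 differ by more, and in the direction opposite to the gene. The log2 difference of the total is 0.32 against −0.468 for Rpl30 itself, and −1.125 against 1.393 for Cdh11 itself.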

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

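The genes and lists examined in this part were those named or called above, so most of them were picked by the results and are not independent. The rate that chance gives is therefore only a rough guide here. Of 202 groups of libraries examined with Dixon's test, 12 held a library set apart from the others of its group, where chance gives about 1 in 20, or 10.1. Of the 12, 7 were in WT A. There Cxcl13 stood at 4.28 on the log2(TPM + 1) scale with the nearest other WT library at 2.38, Klra4 at 2.87 (nearest 0.67), Itga9 at 0.86 (nearest 0.40) and Plvap at 0.78 (nearest 0.39), while Tns4 was low at 4.91 (nearest 6.22) and Gsta2 at 1.97 (nearest 3.49). The mitochondrial genome took 4.68% of TPM in WT A and 6.67% in the nearest other WT library. In WT D, Col6a3 was high at 3.77 (nearest 3.11), and in WT B, Sparc was high at 7.88 (nearest 7.46). Among Lef1KI libraries, Rbpsuh-rs3 was high in B at 3.02 (nearest 0.26), Itga9 was low in B at 0.89 (nearest 1.55), which is close to WT A, and Ccl7 was high in C at 6.31 (nearest 5.07).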

How the results depend on the processing

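Chosen only after the data were seen were the fit to protein-coding genes, the fit with the fibroblast list mean as a covariate and the permutation test of each list. No paired analysis was possible because the columns carry letters that nothing ties to the replicate numbers of the labels, and no source used here says what a letter shared by both groups marks. Lef1 kept its direction and its side of the threshold in every fit run, with a log2 difference of 7.10 to 7.39 when 1 library was left out, 8.63 and 5.34 with pseudocounts of 0.1 and 5, and 7.05 with the covariate. The 1063 changed genes became 628 (without WT E) to 1686 (without Lef1KI A) when 1 library was left out, with 643 without WT B. They became 323 with a filter of 10 TPM, which tests fewer genes, and 2334 with sample quality weights between 0.402 (WT A) and 2.209 (WT B), where the cause was not tested. A test against a log2 fold change of 1 called 48, and adjusted p thresholds of 0.01 and 0.1 gave 446 and 1683, each by its construction. The scalings, the pseudocounts, the filter of 1 TPM, limma without the trend, robust limma and protein-coding genes alone gave between 905 and 1128. Of 81 named genes other than Lef1 that had a call, between 53 (without WT E) and 78 (without Lef1KI A) kept it when 1 library was left out.

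Camera called 10 lists, 8 to 12 with 1 library left out, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 0 by the exact permutation test (16 at an unadjusted p under 0.05, lowest adjusted p 0.109). Fry, which does not compare a list with other genes, called 9 lists, all 9 higher, of which 4 were among camera's 10, and it called 0 of camera's 6 lower lists. Which property of the lists ends the calls with an estimated correlation was not tested. With the fibroblast list mean as a covariate, limma called 8 genes (5 higher, 3 lower). That mean lay between 5.16 and 6.40 in Lef1KI and between 3.40 and 4.06 in WT, so by construction the covariate takes up most of the group difference, and none of those 81 named genes kept its call. There the log2 difference reversed for Nkd2 (−0.029), Mylk (−0.44), Bmp4 (−0.36), Tgfbr2 (−0.059), Saa3 (−0.51), Nr4a1 (−0.21), Nrp1 (−0.23) and Best1 (−0.19). Of camera's 10 lists, 2 kept their call with the covariate, 3 lost it in the same direction and 5 reversed. Camera's direction reversed for the G2/M (adjusted p 7.17e-12, now higher), transition (0.731), sterol (0.133), fibroblast (0.951) and ribosomal lists (0.894). The fibroblast list was adjusted there for its own mean, so the loss of its call was fixed by construction. TPM keeps no depth, so how far counting error limits the genes with low values is unknown.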

Other observations

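Chosen only after the result was seen were the tests of symbol families, of joint variation of the fibroblast genes, of both scaling explanations, of fibroblast against leukocyte genes, of family totals, of genome windows and of the splits over genes that pass the authors' filter in any grouping. Genes with the symbol stems Adamts, Mmp, Col and Ccl were called higher more often than other genes. Among 214 families of genes that share a symbol stem, each tested in both directions by a one-sided Fisher's exact test (428 tests), 4 passed after Benjamini-Hochberg adjustment, all higher in Lef1KI. Of 9 Adamts genes, which encode secreted metalloproteases, 7 rose (Fisher's exact adjusted p 4.82e-05), among them Adamts2, from 2.82 ± 0.637 to 20.9 ± 8.82 TPM, and Adamts5, from 4.78 ± 1.35 to 12 ± 3.91 TPM. Of 11 matrix metalloprotease genes 6 rose (Fisher's exact adjusted p 0.00338), with Mmp3 rising from 120.1 ± 52.1 to 343 ± 127 TPM and Mmp11 from 1.56 ± 0.621 to 5.68 ± 1.68 TPM. Of 10 Ccl chemokine genes 6 rose (Fisher's exact adjusted p 0.00217), including Ccl11, from 0.315 ± 0.173 to 6.72 ± 4.63 TPM, and Ccl19, from 0.775 ± 0.171 to 8.06 ± 4.26 TPM, whereas of 10 Cxcl chemokine genes 2 rose (Fisher's exact p 0.142, not past the threshold after adjustment). Of 30 collagen genes 12 rose (Fisher's exact adjusted p 4.82e-05). Genes of a family are not independent of each other, and the fibroblast list was higher in the same 5 libraries.

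Fibroblast and endothelial genes were higher in Lef1KI, and a candidate explanation is cells of these types in the GFP-negative gate, which the GFP-positive gate of WT would remove. Within groups the 16 fibroblast genes, 0 of them in another list and 15 at 1 TPM or more in WT, varied together at percentile 100 of 10000 matched random lists (mean pairwise correlation 0.74, random 95th percentile 0.205), which such cells need but a shared gene programme would also give. The most abundant of them, Mgp and Gsn, had 2263 ± 911 and 574 ± 112 TPM in Lef1KI and 583 ± 261 and 357 ± 32.9 TPM in WT. The tables argue against scaling as the whole cause (median log2 difference 1.805 after median centring) and against 1 library (at least 14 members rose with any library left out). The fibroblast median lay above the leukocyte median by 1.889. However, 3 of the 6 leukocyte genes were under 1 TPM and of the other 3 Lyz2 rose. The Schwann and neural list, with a median level of 11.8 TPM in WT, had a median log2 difference of −0.259. Of its 8 genes 5 were lower and 3 higher. Whether these 8 genes were expressed by the sorted cells or by others is unknown. They therefore cannot decide whether a lower share of sorted cells raised all other cell types alike. The cartilage and muscle list had a median of −0.105, at a median level of 1.8 TPM in WT. A lower share of sorted cells, fibroblast and endothelial cells in the gate, a response to Lef1 and a difference between the mouse lines stay open. The last 2 were not tested, since gate and genotype change together in every library.

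Gene copies stood out among the largest differences, and reads divided differently between a gene and its copy may account for part of them. In 23 of 31 families (74.2%) the related gene moved against its copies, just short of the bound set in advance, so the test decides neither way. These were 16 of the 17 families whose copies were lower in Lef1KI but 7 of the 14 whose copies were higher, and the directions of gene and copies were associated (two-sided Fisher's exact p 0.0109). Of the 7 related genes that passed the threshold and moved against their copies, 5 (71.4%) had a family total that differed by less than 0.5 of their own log2 difference, which decides nothing, because adding copies that moved the other way draws a total toward 0 by construction. Sequence differences between the mouse lines at these copies were not tested and stay open.

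More genes were higher than lower in Lef1KI (84.5%). Scaling stays open as an explanation, because higher and lower calls balanced at an offset of 0.19 between the groups on the log2 scale, which lies within 1 SE of the difference of 0.159 ± 0.067 (SE) between the mean library medians. The 797 genes called higher outside the fixed lists followed the fibroblast list mean within groups, with a median correlation of 0.572 against 0.15 for matched sets of uncalled genes, a difference of 0.422. This is consistent with a part of the rises sharing the source of the fibroblast genes, whether other cells or a programme within the sorted cells, and a response to Lef1 stays open and untested.

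The real split gave the highest gene count of the 100 splits of the 9 libraries that were drawn, 1 of 100, with 1063 genes against at most 346 in another split and 0 in 95 others. The authors' filter used the real groups, which favours the real split. Among the 11543 genes that pass that filter in any grouping, which leaves out 585 of the 1063, the real split called 274, and 3 of the 100 splits called as many, the real one included. The other 2 called 277 and 446, and both set WT A, Lef1KI B, Lef1KI C and Lef1KI E against Lef1KI A and the other WT libraries. Over these genes the 3 of 100 lay under a share of 5%, but the real split was not the highest. Not every possible split was drawn, and those left out could change that share. Chance is therefore less likely for the gene count but is not excluded. For the number of lists chance cannot be excluded either, since 67 of the 100 splits gave as many as the real 10. The highest other split gave 18 lists. Changed genes clustered in no 10 Mb window of the genome at the adjusted threshold (lowest Fisher's exact adjusted p 0.12), which does not exclude a cluster, since 9 of 31 genes had changed on chromosome 2 from 80000001 to 90000000 (unadjusted p 0.000521) and 13 of 61 on chromosome 18 from 60000001 to 70000000 (0.000899).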
